A study of Mus musculus with 20 samples.

How the data were processed

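The series holds 20 arrays of mouse embryos read in 2 colours, each with Ptdsr-/- RNA in one channel and a pool of Ptdsr+/+ RNA in the other. Per the labels, the mutant is channel 1 throughout and carried Cy5 on 10 arrays and Cy3 on 10. Ages were E11.5 (4 arrays), E12.5 (12 arrays, numbered 1 to 11 and 13) and E13.5 (4 arrays). The design text gives biological replicates for E12.5 and technical replicates for the other ages, and which arrays share an embryo is not given. Each array is therefore the unit of the tests, and the control pool counts as 1 sample whose own spread is left out.

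The authors deposited 1 value per probe and array, a log2 ratio of the 2 channels. The scanner, spot filter and normalisation are not given in the sources used here. Many of the deposited log2 values fall on ratios of small whole numbers plus 1 constant per array, as dim spots under a single scaling factor per array would. Array medians run from -0.202 to 0.843. Between 8.23% and 52.7% of an array's values were ratios of whole numbers up to 10, to within 0.001 on the log2 scale, against 0.706% to 3.28% for shifted constants. Between 60 and 898 values per array lie over 12 from 0, at a repeated value that a floored channel would give with a ratio of 1e+05, and were treated as missing. Spot intensities were not used here, so signal over background is unknown.

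The direction of the ratios was to be taken from the correlations between dye orientations and from the targeted gene, and these did not settle it, so the deposited sign was kept and every group of genes was also tested with the sign turned on the arrays whose mutant carried Cy3. The floored value is positive on the 10 arrays with the mutant in Cy5 and negative on the 10 with the mutant in Cy3, looked at afterwards. A ratio of Cy5 to Cy3, floored in Cy3 and turned for the swapped arrays, would look like this, which makes mutant over wild type the likelier reading, though others are possible.

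Of 20355 probes, 14030 had 1 gene symbol, 5 had several and 6320 had none. Gene names came from the probe annotation, matched by gene identifier to current symbols for 13994 probes, and 36 kept the annotation's symbol. No genome build applies to the probes, so no positions are given. Each array was centred on the median of its probes. Probes needed a value on at least 8 of 12 arrays at E12.5 and at least 3 of 4 at the other ages, and probes of a gene were averaged, which left 8089 genes at E12.5 and 7014 in the fit of all arrays.

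Ratios were tested against 0 with limma 3.58.1 in R 4.3.3, with a term for dye orientation and Benjamini-Hochberg adjusted p under 0.05. E12.5 was fitted alone. E11.5, E13.5 and the contrasts between ages came from 1 fit of all 20 arrays with a mean per age, since 4 arrays leave few residual degrees of freedom. The value of a gene is the fitted log2 ratio with its standard error, or its mean with SD where so marked, and the 2 differ where arrays of 1 orientation are missing. Named genes were Jmjd6, genes past the threshold, and, where fewer than 5 passed in a direction, the 5 with the smallest p. Gadd45b, Xpc, Cd68, Hba-x and the named members of groups at E13.5 were chosen after their values were seen.

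Before the data were examined, 29 lists of genes were fixed, and 26 with at least 5 measured members were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists. Camera compares a list with the other genes. An estimated correlation and fry, which asks whether a list moves one way on balance, were alternatives, and fry used genes measured on every array. Tests of the lists on the contrasts between ages, and their alternatives, were added after the data were seen. On simulated data with the same missing values, in 20 runs, changes of 1 on the log2 scale were recovered for 3.50% of genes at E11.5, 21.2% at E12.5 and 3.70% at E13.5, and changes of 2 for 48.0%, 84.1% and 50.9%. A list shifted by 0.5, the mRNA splicing genes, was found in 20 of 20 runs at each age. The simulated noise was independent between genes and had 1 spread per gene over all arrays. It therefore does not show how often a list of correlated genes, or a smaller list, would be found.

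Alternatives fixed beforehand were no centring, arrays scaled to 1 spread, no dye term, stricter and looser filters on missing values, single probes, a robust prior, turned signs, each array left out, a stricter threshold, assumed sets of arrays at E12.5 and a block for the array number. Added after seeing the data were floored values kept at the most extreme measured value, low-number ratios removed, centring on 796 probes bright on every array, removal of each array's brightness trend, and leaving out arrays 9, 10 and 13 of E12.5 and array 1 of E13.5, whose bright probes lay over 0.6 from the array median. Whether the array numbers pair the ages is not known: over 12 same-number pairs the correlation of deviations ran from -0.0360 to 0.116, with 1 above 0.1. Pairs of unlike number were not set beside them. A filter on dim probes was planned and needs intensities that are not held. Brightness therefore stands for the share of arrays on which a probe had a value that was neither floored nor a low-number ratio.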

Results

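The series compared mouse embryos that lack Ptdsr with wild-type controls on 20 arrays read in 2 colours. Ptdsr, now named Jmjd6, was first described as a receptor for phosphatidylserine on dying cells and is now known as a nuclear oxygenase of the JmjC family. Embryos were taken at 3 ages, with 4 arrays at E11.5, 12 at E12.5 and 4 at E13.5. Each array compared Ptdsr-/- RNA with a pool of Ptdsr+/+ RNA, and the mutant carried Cy5 on 10 arrays and Cy3 on 10. The labels state biological replicates at E12.5 and technical replicates alone at E11.5 and E13.5, so the p-values of these 2 ages rest on 1 preparation each and do not describe embryos. The spread they use comes from the fit of all 20 arrays, those of E12.5 included, so they do not measure repeatability at 1 age either. Arrays held between 11824 and 19474 values of 20355 probes. The number of arrays limits the precision: the median standard error of a gene was 0.50 at E11.5, 0.33 at E12.5 and 0.49 at E13.5 on the log2 scale.

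Which genotype stands above the line in the deposited log2 ratios was not given in the sources used here, and the values did not settle it. At E11.5 arrays of opposite dye orientation had a median Spearman correlation across probes of -0.125, with 4 of 4 pairs below 0, against 0.127 for arrays of 1 orientation. At E13.5 opposite orientations gave 0.0497, with 0 of 4 pairs below 0, and at E12.5 21 of 36 pairs lay below 0. Probes are not independent replicates. The targeted gene, Jmjd6, lay below 0 on 2 of 2 arrays of each orientation at E11.5 and on 5 of 6 of each at E12.5. At E13.5 it averaged 0.68 with the mutant in Cy5 and -0.22 with it in Cy3. Floored values were positive on 10 of 10 arrays with the mutant in Cy5 and negative on 10 of 10 with it in Cy3, which makes mutant over wild type the likelier reading without settling it. Values are therefore given as above or below 0 in the deposited sign, and groups of genes also with the sign turned on the arrays whose mutant carried Cy3.

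Jmjd6, the targeted gene, lay below 0 on 4 of 4 arrays at E11.5 and on 10 of 12 at E12.5, and above 0 on 3 of 4 at E13.5. Its mean log2 ratio was -0.65 ± 0.26 (SD, n = 4 arrays) at E11.5, -0.91 ± 1.46 (n = 12) at E12.5 and 0.23 ± 0.73 (n = 4) at E13.5. It passed at no age by limma, with adjusted p = 1, 0.833 and 1. With the sign turned its value was above 0 at E11.5 and E12.5, at 0.15 and 0.42. In the fit without array 1, which applied the filter on missing values anew, its value at E13.5 was -0.20. The probes for Jmjd6 gave -1.04 ± 1.78 (SD, n = 4) and -0.24 ± 2.18 (n = 3) at E11.5, and after the dye term the value from the latter lay at 0.0024. Taken singly, these probes were below 0 on 3 of 4 and 2 of 3 arrays. The part of the transcript that the mutant allele still makes is not given in the sources used here.

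The comparison at E13.5 asks how mutant and control embryos differ at the latest age collected. Genes for ribosomal proteins and for mitochondrial respiration lay above 0 as groups, and genes for the proteins that fetal liver and yolk sac secrete lay below 0. With an estimated correlation the first 2 did not pass, with adjusted p = 0.107 and 0.0664, and the third had adjusted p = 0.00517. In the fit of all arrays the estimate was 0.258 and 0.0508 for the first 2. For the third it was -0.0075 and counted as no correlation, so on that point the test was no stricter than the preset of 0.01. Alb, the serum albumin made by fetal liver, stood at -1.47 ± 0.27 (SE of the fit, n = 4 arrays), Afp, the fetal serum protein of liver and yolk sac, at -1.47 ± 0.31, and Rbp4, the retinol carrier, at -1.48 ± 0.39. Each of these 3 was below 0 on 4 of 4 arrays. None passed over all genes, with adjusted p = 0.189 for Alb, 0.417 for Afp and 1 for Rbp4.

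Of 28 measured hepatocyte and yolk sac genes, 19 lay below 0 and 9 above at E13.5, with a median of -0.35. Fgb, a fibrinogen chain, stood at -1.57 ± 0.62 (SE, n = 3 arrays), Serpina1b, a protease inhibitor of plasma, at -1.02 ± 0.47 (n = 4) and Serpina6, the corticosteroid carrier, at -0.81 ± 0.35 (n = 4), while Serpinf2, the inhibitor of plasmin, was at 0.86 ± 0.40 (n = 4). The group passed the camera test of limma, with adjusted p = 1.83e-04, and adjusted p = 0.00517 with an estimated correlation. That estimate was below 0 and counted as no correlation. Adjusted over the list alone 3 members passed, Alb, Afp and Rbp4, against 0 over all genes. The median depended on array 1, without which it was -0.19 with adjusted p = 0.00144, or -0.13 with adjusted p = 0.00344 when the arrays of E12.5 that stand apart were left out too, and it was -0.67 with adjusted p = 2.18e-04 centred on bright probes, where the median of all genes was -0.29. With the sign turned the median was -0.13 and adjusted p = 0.695.

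Ribosomal protein genes, which build both subunits of the ribosome, had a median of 0.65 at E13.5, with 45 of 48 above 0. Rpl7 stood at 1.02 ± 0.14 (SD, n = 4 arrays), Rps4x at 1.04 ± 0.28 and Rps20 at 0.92 ± 0.06, each above 0 on 4 of 4 arrays. The group passed with adjusted p = 1.3e-15, but had adjusted p = 0.107 with an estimated correlation and 0.184 by fry. Genes of oxidative phosphorylation, the respiratory chain and ATP synthase, had a median of 0.39 with 46 of 57 above 0, among them Ndufs6 at 0.81 ± 0.24 and Ndufa7 at 0.80 ± 0.28, subunits of complex I. This group had adjusted p = 5.03e-06, but adjusted p = 0.0664 with an estimated correlation and 0.184 by fry. Adjusted over the list alone 0 members of either group passed, and 0 over all genes. With the sign turned the medians were 0.0035 and 0.052, with adjusted p = 0.726 and 0.671. With the brightness trend of each array removed the medians were 0.43 and 0.26. Centred on bright probes, which put the median of all genes at -0.29, the medians were 0.34 and 0.07.

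Genes of the cell cycle and DNA replication had a median of 0.26 at E13.5, with 32 of 48 above 0. Cdk1, the mitotic kinase, stood at 0.75 ± 0.15 (SD, n = 4 arrays), Top2a, the topoisomerase of dividing cells, at 0.82 ± 0.17 and Rpa1, which binds single-stranded DNA, at 1.33 ± 0.85, while Ccnb2, a mitotic cyclin, was at -0.80 ± 0.91. The group had adjusted p = 0.0241, but adjusted p = 0.210 with an estimated correlation and 0.341 by fry. By array, less the median of all genes, the group averaged 0.40 with the mutant in Cy5 and 0.05 with it in Cy3. Its adjusted p was 0.0545 or more in 3 of the 4 fits that each left out an array of E13.5, its median was -0.050 when arrays were centred on bright probes, and with the sign turned it was 0.14 with adjusted p = 0.338. Markers of red blood cells had a median of -0.05 and a mean of 0.03 over 21 genes with adjusted p = 0.921, and Hba-x, an embryonic globin, stood at 1.03 ± 0.22. The other 21 groups tested at E13.5 did not pass, with adjusted p from 0.0823 for neural progenitor genes to 0.900 for cartilage and bone genes. Some of them passed in alternatives, among them neural progenitor and mRNA splicing genes above 0 with low-number ratios removed, at 0.68 and 0.40.

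Among single genes at E13.5, limma gave 0 of 7014 past the adjusted threshold, while 311 had an unadjusted p under 0.05. The genes with the smallest p above 0 were Narf at 1.39 ± 0.31 (SE, n = 4 arrays), Chrac1, a subunit of chromatin remodelling complexes, at 1.72 ± 0.40, Shcbp1 at 1.44 ± 0.37, Pabpc1, the cytoplasmic poly(A) binding protein, at 2.44 ± 0.65 and Rcc1, the exchange factor of Ran, at 1.15 ± 0.32. Below 0, after Alb, Afp and Rbp4, came Arpp21, a phosphoprotein of neurons, at -1.89 ± 0.52 and Arhgap25, a regulator of Rac, at -2.001 ± 0.57. None of these passed. Array 1 carried some of the values: without it the plain mean over arrays was 0.88 for Pabpc1, 0.95 for Shcbp1, -1.19 for Arpp21 and -0.65 for Arhgap25. Tested per probe, 1 of 12562 probes passed, a probe for Afp at -2.16 ± 0.30 (SD, n = 4 arrays) with adjusted p = 0.0103, while the other probes for Afp lay at -0.77 ± 0.32 (n = 4) and -0.77 ± 1.16 (n = 3), of which the first did not pass and the second was not tested. Alb and Afp passed when arrays were centred on bright probes, with adjusted p = 0.0325 and 0.0240, but that centring put the median of all genes at -0.29. Both had adjusted p = 0.0332 when low-number ratios were removed, which left 3720 genes to test and put each of them at -1.44.

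**Figure D1:**
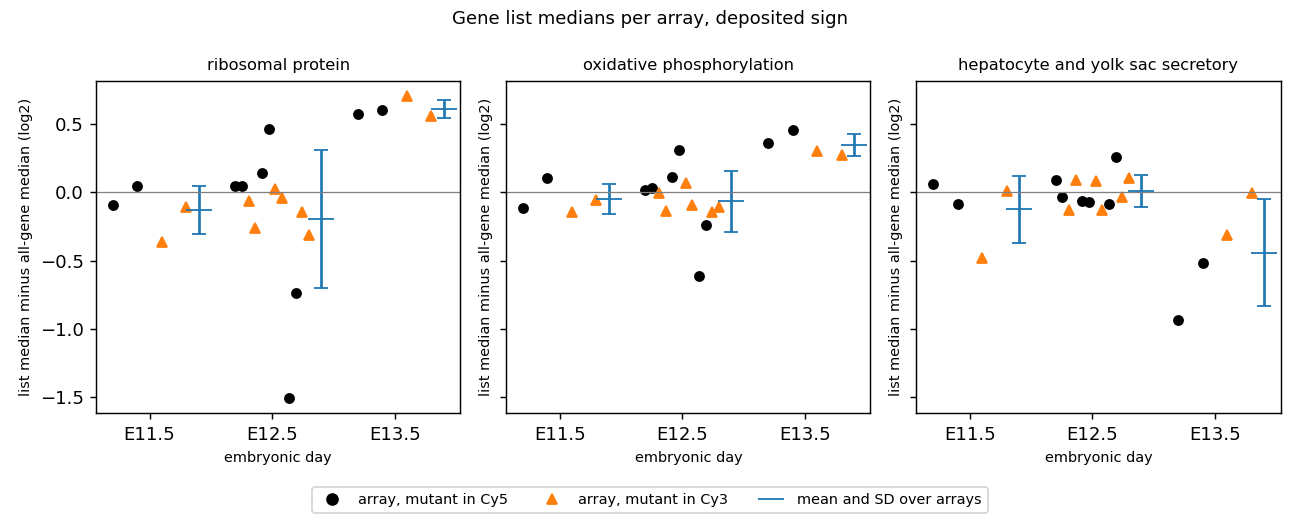
Median log2 ratio of the ribosomal protein, oxidative phosphorylation and hepatocyte and yolk sac genes on each array, less the median of all genes on that array, in the deposited sign and by age, with the dye of the mutant marked and the mean and SD over arrays. At E13.5 the means over 4 arrays were 0.61, 0.35 and -0.44.

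**Figure D2:**
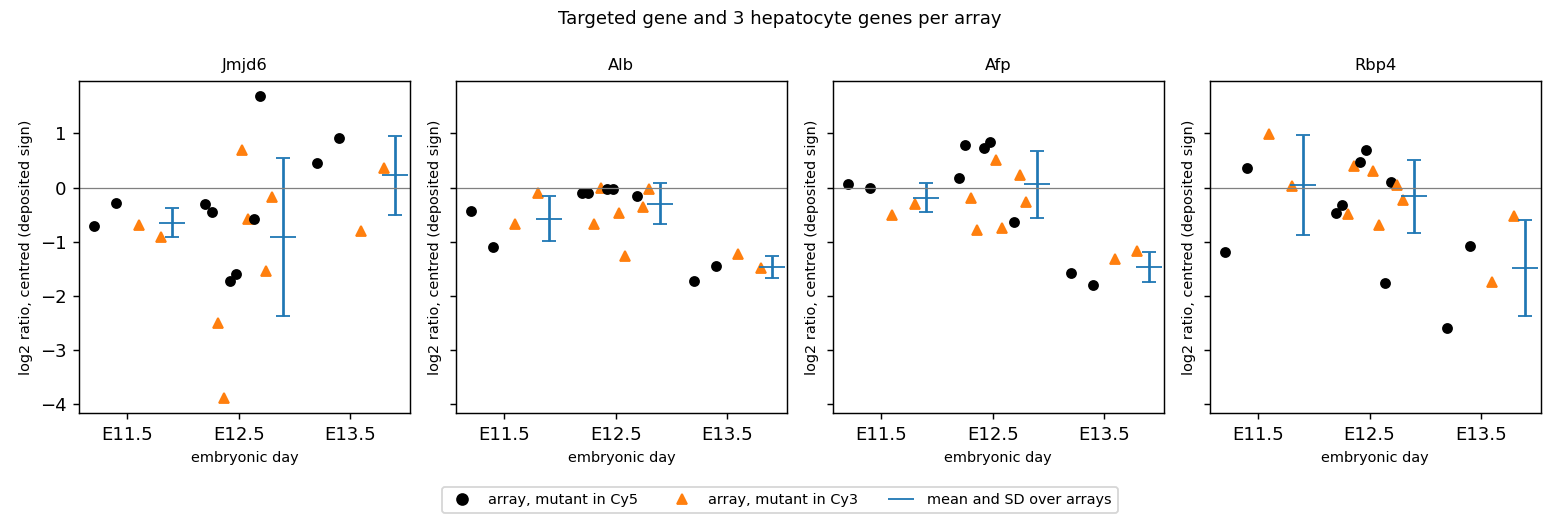
Log2 ratio of Jmjd6, Alb, Afp and Rbp4 on each array, in the deposited sign and by age, with the dye of the mutant marked. Alb, Afp and Rbp4 were below 0 on 4 of 4 arrays at E13.5.

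At E12.5, the age with biological replicates, no gene and no group of genes passed. The smallest p belonged to Rab3gap1, which acts on the vesicle protein Rab3, at -2.85 ± 0.36 (SE, n = 8 arrays) after the dye term, while its plain mean was -1.50 ± 2.61 (SD). Also below 0 were Ttyh3, a chloride channel, at -2.33 ± 0.39, Alox12e, an epidermal lipoxygenase, at -1.76 ± 0.32, Tcp11x2 at -1.64 ± 0.32 and Evl, an actin regulator, at -1.67 ± 0.31. Above 0 were Rnf2, a Polycomb ubiquitin ligase, at 1.76 ± 0.37, Mlxip, a glucose-sensing transcription factor, at 1.34 ± 0.33, Lamc3, a laminin chain, at 1.46 ± 0.36, Arhgap33 at 1.25 ± 0.30 and Hk2, a hexokinase, at 1.02 ± 0.26. By limma 0 of 8089 genes passed, 473 had an unadjusted p under 0.05, and the smallest adjusted p was 0.110, for Rab3gap1. Without array 10, which left 7444 genes, Rab3gap1 and BC031181 passed, with Rab3gap1 at an unchanged -2.85 and adjusted p = 0.0498. Mlxip lay at the same 0.64 without array 9 and without array 10, since a probe then failed the filter on missing values. Because the arrays that share an embryo are not given, and the control pool is 1 sample, these p-values may be too small.

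No group of genes passed at E12.5. Genes of the p53 response had the smallest adjusted p, 0.330, with 13 of 15 below 0 and a median of -0.33. Gadd45b, a stress gene, stood at -0.63 ± 1.34 (SD, n = 12 arrays) and Xpc, a DNA damage sensor, at -0.52 ± 0.61 (n = 8). Ribosomal protein genes had a median of -0.15 with adjusted p = 0.347, hepatocyte and yolk sac genes -0.08 with 0.854 and oxidative phosphorylation genes -0.09 with 0.854. Genes of macrophages and phagocytosis, the process first assigned to Ptdsr, had a median of -0.06 over 30 genes with adjusted p = 0.854. Genes of apoptosis had -0.09 with 0.854 and genes of the oxygenase and histone demethylase family of Jmjd6 -0.16 with 0.854. The medians of macrophage, apoptosis and splicing genes lay below 0 while their tests leaned above 0. Genes of mRNA splicing, a process in which Jmjd6 acts, had a median of -0.01 with adjusted p = 0.707, but passed above 0 without arrays 9, 10 and 13, which stand apart, at 0.20 with 38 of 55 above 0 and adjusted p = 0.0222, and without arrays 9 to 13, at 0.18 with adjusted p = 0.0278. Turned in sign, the smallest adjusted p of any group was 0.498. Ribosomal protein genes passed without array 6, the highest, with a median of -0.23 and adjusted p = 0.0107. Their array medians less the median of all genes averaged -0.19 over 12 arrays, -0.07 without array 9, the lowest at -1.51, and -0.0077 without arrays 9 and 10. The passes of ribosomal protein and splicing genes without some arrays used the preset correlation alone. Over all 12 arrays each of these groups had adjusted p = 0.827 by camera with an estimated correlation.

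At E11.5, the earliest age, no gene and no group passed either. Above 0 with the smallest p were Foxi1, a forkhead factor of ear and branchial ectoderm, at 2.24 ± 0.56 (SE, n = 3 arrays), Per3, a clock gene, at 1.70 ± 0.47 (n = 4), Cox19, which helps assemble cytochrome oxidase, at 2.01 ± 0.56 (n = 3), Pdlim1 at 2.03 ± 0.60 (n = 3) and Prox1, a factor of lens, liver and lymphatic cells, at 1.05 ± 0.32 (n = 3). Below 0 were Tmco5b at -1.89 ± 0.47 (n = 4) and, on 3 arrays each, Top3a, a DNA topoisomerase, at -2.69 ± 0.75, Ly6k at -2.67 ± 0.76, Psg19, a glycoprotein of placenta, at -2.27 ± 0.64 and Kctd12 at -1.81 ± 0.52. Single arrays carried many of these values: without 1 array the plain mean was 0.24 for Pdlim1, whose arrays lay at 0.22, 0.26 and 4.94, 0.66 for Per3, 0.52 for Prox1, 1.22 for Cox19, 2.96 for Foxi1, -0.97 for Tmco5b, -1.76 for Top3a, -1.53 for Ly6k and -1.31 for Psg19. By limma 0 of 7014 genes passed, 142 had an unadjusted p under 0.05 and the smallest adjusted p was 1. With the sign turned Foxi1, Per3, Cox19, Pdlim1, Prox1, Ly6k and Psg19 changed side, and Cep128, a centrosome gene, passed with adjusted p = 0.00593. The smallest adjusted p of a group was 0.620, for ribosomal protein genes at a median of -0.08, which passed at -0.11 with low-number ratios removed or without the arrays that stand apart, and with the sign turned it was 0.139, for red blood cell genes. The passes of ribosomal protein genes used the preset correlation alone, and none of the arrays that stand apart is of E11.5. Over all arrays that group had adjusted p = 0.900 by camera with an estimated correlation.

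The contrasts between ages ask whether the ratio of mutant to control differed with age. Relative to E12.5, ribosomal protein genes at E13.5 were higher in the deposited ratio by a median of 0.86, with 44 of 48 above 0, and oxidative phosphorylation genes by 0.50, with 46 of 57. Hepatocyte and yolk sac genes were lower, with a median difference of -0.27 and 20 of 28 below 0. These groups passed with adjusted p = 1.79e-14, 3.23e-05 and 0.00407, and with an estimated correlation had adjusted p = 0.133, 0.108 and 0.0303. For hepatocyte and yolk sac genes that estimate was below 0 and counted as no correlation. With the sign turned none passed, each with adjusted p = 0.956. Relative to E11.5, ribosomal protein genes at E13.5 differed by 0.76 with adjusted p = 2.26e-13 and oxidative phosphorylation genes by 0.34 (adjusted p = 2.94e-04). With an estimated correlation both had adjusted p = 0.166, with the sign turned they were at -0.052 and 0.082 with adjusted p = 0.623 and 0.904, and centred on bright probes oxidative phosphorylation genes lay at -0.011. No group passed between E12.5 and E11.5, with a smallest adjusted p of 0.682. Because the arrays of E13.5 and of E11.5 each repeat 1 preparation, these p-values describe arrays and not a difference between embryos of 2 ages.

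By array, list medians less the median of all genes on the array showed the same differences. Ribosomal protein genes lay between 0.56 and 0.71 on the 4 arrays of E13.5, between -0.37 and 0.05 on those of E11.5 and between -1.51 and 0.47 on the 12 of E12.5, where without the arrays that stand apart the lowest was -0.26. Oxidative phosphorylation genes lay between 0.28 and 0.46 at E13.5, between -0.14 and 0.11 at E11.5 and between -0.61 and 0.31 at E12.5. Hepatocyte and yolk sac genes lay between -0.94 and -0.0040 at E13.5, between -0.48 and 0.06 at E11.5 and between -0.13 and 0.26 at E12.5. No test between ages over embryos can be made from these arrays.

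Single genes did not pass in any contrast. Between E13.5 and E12.5, Afp differed by -1.54 ± 0.36 (SE) and Alb by -1.18 ± 0.31, and Ttyh3 by 3.75 ± 0.90, Chrac1 by 1.78 ± 0.49 and Stx12, a vesicle fusion protein, by -3.63 ± 0.99. Between E12.5 and E11.5, Foxi1 differed by -3.02 ± 0.63, Mrap, a partner of melanocortin receptors, by 2.44 ± 0.61 and Sema3c, a guidance protein, by 1.90 ± 0.53. Between E13.5 and E11.5, Top3a differed by 4.26 ± 1.06, Mrps23, a mitochondrial ribosomal protein, by 2.30 ± 0.58 and Foxi1 by -3.07 ± 0.73. Jmjd6 differed by 1.14 ± 0.65 between E13.5 and E12.5. By limma 0 of 7014 genes passed in each contrast, with 382, 239 and 202 genes at an unadjusted p under 0.05, in that order, and smallest adjusted p = 0.886, 0.999 and 0.999.

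Across 7014 genes, the ratios at 2 ages were nearly uncorrelated in the deposited sign. Pearson's correlation was -0.0493 between E11.5 and E12.5, 0.0310 between E12.5 and E13.5 and -0.0103 between E11.5 and E13.5, and Spearman's was -0.0472, 0.0252 and -0.0224. The share of genes with 1 sign at both ages was 48.7%, 49.7% and 48.8%. Genes are not independent replicates, and with 0 genes past the threshold at each age there was no overlap of calls to compare. Technical repeats themselves correlated weakly, with a median Spearman across probes of 0.127 at E11.5 and 0.118 at E13.5 in 1 orientation. In opposite orientations the medians were -0.125 and 0.0497. Values this noisy would correlate weakly in any case, so they cannot tell whether the ratios differ between ages.

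**Figure D3:**
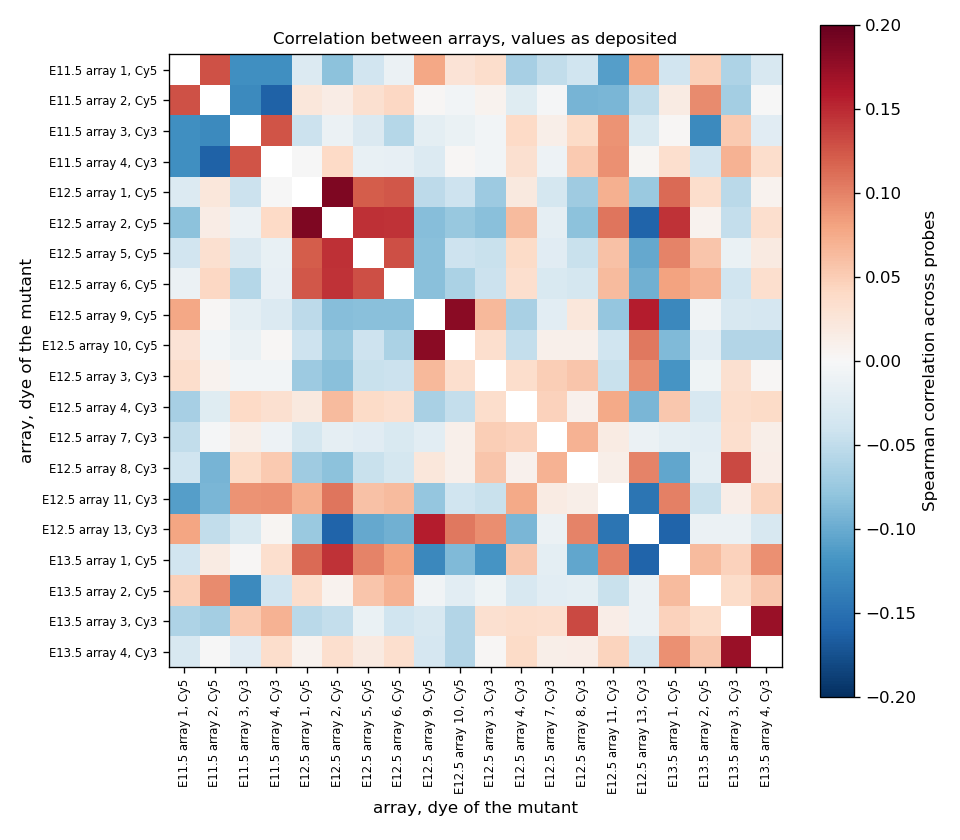
Spearman correlation across probes between each pair of the 20 arrays, in the deposited sign, ordered by age and dye of the mutant. At E11.5 pairs of opposite orientation lay between -0.162 and -0.123, and pairs of 1 orientation between 0.126 and 0.128.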

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

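The tests against brightness-matched lists, the comparison of array values between ages, the tests of groups of genes on the contrasts and the checks of centring were chosen after the results were seen. The counts over splits and sign patterns were planned, but those for groups in the contrasts rest on the tests added afterwards.

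Ribosomal protein and oxidative phosphorylation genes differed between ages by the test of the contrast over arrays, with median differences of 0.86 and 0.50 between E13.5 and E12.5 (adjusted p = 0.133 and 0.108 with an estimated correlation) and of 0.76 and 0.34 between E13.5 and E11.5 (adjusted p = 0.166 for both). Judged without intensities, the values argue against brightness as the whole cause, within limits. Of 10000 random lists matched on brightness, 0 lay as far above 0 as either group at E13.5. Such lists hold unrelated genes, so the count does not allow for correlation within a group. Bright probes lay 0.135 to 0.639 above the array median at E13.5. On arrays 9 and 10 of E12.5 they lay at -1.14 and -0.932 from it, and array 9 had the lowest ribosomal protein median, -1.51. With each array's brightness trend removed the medians moved from 0.65 to 0.43 and from 0.39 to 0.26. A part of the shift therefore goes with brightness. This measure of brightness has an upper limit, reached by 14 of 48 ribosomal protein and 8 of 57 oxidative phosphorylation genes. In all 425 genes reached it, with a median of 0.28, and among them brightness could not be matched further. Members below the limit had medians of 0.58 and 0.34. A dye effect equal on all arrays is argued against as the whole cause, since the array values of E13.5 stood 1.41 and 1.37 sums of the SDs from the nearer of the other ages. At E12.5, 0 of 12 arrays for ribosomal protein and 1 of 12 for oxidative phosphorylation genes lay as far above 0 as the lowest array of E13.5. A dye effect particular to E13.5 stays open only if the values are Cy5 over Cy3, since in mutant over wild type, the likelier reading, it would part the 2 orientations, which lay at 0.59 and 0.64 and at 0.41 and 0.29, and the single RNA preparation stays open in both readings. A change with genotype may exist but was not tested over embryos.

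Hepatocyte and yolk sac genes differed between E13.5 and E12.5 by a median of -0.27 over arrays (adjusted p = 0.0303 with an estimated correlation). The estimate was below 0 and counted as no correlation. The tables argue against brightness as the whole cause, since 0 of 10000 matched lists lay as far below 0 at E13.5, and with the brightness trend removed the median was -0.35, as before. If the values are Cy5 over Cy3, a dye effect equal on all arrays stays open, since the array values of E13.5 stood only 0.498 sums of the SDs from those of E11.5 and 0.884 from those of E12.5, while in mutant over wild type, the likelier reading, it would cancel in a mean over both orientations. At E13.5 the orientations parted, at -0.73 with the mutant in Cy5 and -0.16 with it in Cy3, so the shift was larger with the mutant in Cy5. A lower share of liver or yolk sac in the mutant preparation may account for the values, as may genotype, and neither was tested. The median was -0.19 without array 1 of E13.5.

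Alb was below 0 on 19 of 19 arrays that measured it when arrays were centred on all probes, but with a highest value of only -0.02. The pattern depended on that choice: Alb was below 0 on 16 of 19 arrays as deposited, on 17 of 19 centred on bright probes, on 17 of 19 with the brightness trend removed and on 17 of 17 with low-number ratios removed. Centred on all probes, 2 of 100 sign patterns, the real one included, gave as many genes of 1 sign (1 real, 1 the highest other), which does not exclude chance when the sign itself moved with the centring. At E13.5 Alb was below 0 on 4 of 4 arrays under each of these choices. Its array values at E13.5 stood 1.43 sums of the SDs from those of E11.5, the nearer age, which argues against a dye effect equal on all arrays as the whole cause of the E13.5 values, though not as a part of the sign, and the preparation stays open. At E12.5, 1 of 11 arrays lay as far below 0 as the E13.5 array nearest to 0.

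Per3 at E11.5 had an array far from the others, array 3 at 4.81, with a gap of 0.835 of the range. Chance marks about 1 in 20 such groups, and 1 of 19 tested was marked, while 9 groups of 3 arrays were not tested.

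Regrouping the arrays gave no verdict on chance. Where the real count of genes was 0, every regrouping gives as many: 100 of 100 sign patterns at E12.5 (highest other 0), 100 of 100 splits between E12.5 and E11.5 (highest other 8), 100 of 100 between E13.5 and E12.5 (highest other 15) and 35 of 35 between E13.5 and E11.5 (highest other 1). For groups of genes, 3 of 100 splits between E13.5 and E12.5 gave as many as the real 3 (highest other 4), and 7 of 35 between E13.5 and E11.5 gave as many as the real 2 (highest other 3), but these splits exchange repeats of 1 sample with other samples. The 8 sign patterns of 4 arrays are too few for a share under 0.05: real 0 and highest other 2 for genes at E11.5 (8 as large), real 0 and highest other 0 for genes at E13.5 (8 as large), and real 4 and highest other 3 for groups at E13.5 (1 as large).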

How the results depend on the processing

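Of the alternatives, those on floored values, low-number ratios, bright probes, brightness trends and arrays that stand apart and all those of the groups in contrasts between ages were chosen after seeing the data. The ribosomal protein and oxidative phosphorylation groups at E13.5 each passed in 17 of 20 alternatives and the hepatocyte and yolk sac group in 17 of 18. These alternatives reuse the same arrays, and the passes of the ribosomal protein and oxidative phosphorylation groups all kept the preset correlation. Those groups did not pass with an estimated correlation, by fry or with the sign turned. The hepatocyte and yolk sac group did not pass with the sign turned. Of 1716 values, 1635 were marked unchanged, 1245 of them for single genes, which passed neither in the main fit nor in the alternative. For genes and groups the mark means the same direction and side of the threshold. Counts kept it within a fixed ratio, and correlations within their spread over left-out arrays. Spot intensities were not used here, so signal over background is unknown, and the planned filter on dim probes was not run. The hepatocyte and yolk sac group had too few complete genes for fry and for probes with a value on every array. The cause was not tested for any change below, except that fry, single probes and complete probes test other sets of genes. With the array number as a replicate block, 0 genes passed in each contrast between ages, as without it, and whether the numbers pair the arrays is not known.

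With the signs turned, 0 groups passed at E13.5 and 1 gene passed at E11.5. The medians at E13.5 were then 0.0035 for ribosomal protein, 0.052 for oxidative phosphorylation, -0.13 for hepatocyte and yolk sac and 0.14 for cell cycle genes. Turning the signs put Jmjd6 at 0.15 at E11.5 and 0.42 at E12.5, and moved across 0 Foxi1 to -0.052, Per3 to -1.10, Cox19 to -1.37, Pdlim1 to -1.57, Prox1 to -0.38, Ly6k to 0.79 and Psg19 to 0.74 at E11.5, Hk2 to -0.45 at E12.5, and Chrac1 to -0.32 and Rcc1 to -0.039 at E13.5. An estimated correlation left 1 group at E13.5, hepatocyte and yolk sac, whose estimate was below 0 and counted as no correlation. The adjusted p was 0.107 for ribosomal protein genes at 0.65, 0.0664 for oxidative phosphorylation genes at 0.39 and 0.210 for cell cycle genes at 0.26. By fry 0 passed, with adjusted p = 0.184, 0.184 and 0.341. Over all alternatives the adjusted p ran from 5.68e-24 to 0.726 for ribosomal protein, 4.17e-07 to 0.671 for oxidative phosphorylation, 7.38e-07 to 0.695 for hepatocyte and yolk sac and 0.00432 to 0.341 for cell cycle genes.

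Single probes gave 1 pass at E13.5, and probes with a value on every array 2 groups. Low-number ratios removed gave 2 genes and 7 groups at E13.5, 2 groups at E11.5, ribosomal protein and hepatocyte and yolk sac, and 1 at E12.5, cartilage and bone. Centring on bright probes gave 2 genes at E13.5, Alb at -1.79 and Afp at -1.78, where the median of all genes was -0.29. With low-number ratios removed they lay at -1.44 and -1.44. Leaving out the arrays that stand apart gave 1 group at E11.5, ribosomal protein, 1 at E12.5, mRNA splicing, and 7 at E13.5. Leaving out the assumed sets 5 to 8 and 9 to 13 of E12.5 each gave 1 group, ribosomal protein and mRNA splicing. The cell cycle group at E13.5 did not pass with probes on every array (0.36), every probe the fit could estimate (0.14), assumed sets averaged (0.23), floored values kept (0.25) or brightness trends removed (0.041), and lay at -0.050 centred on bright probes.

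With 1 array left out, the count of genes ran from 0 to 0 at E11.5 and E13.5 and in each contrast, and from 0 to 2 at E12.5. Groups ran from 0 to 0 at E11.5, 0 to 1 at E12.5 and 3 to 4 at E13.5. Medians at E13.5 ran from 0.62 to 0.72 for ribosomal protein, 0.31 to 0.47 for oxidative phosphorylation, -0.48 to -0.19 for hepatocyte and yolk sac and 0.24 to 0.28 for cell cycle genes. Jmjd6 ran from -1.45 to -0.12 at E11.5, -1.13 to -0.65 at E12.5 and -0.20 to 0.37 at E13.5, and its difference between E12.5 and E11.5 from -0.59 to 0.74. Leaving out an array can also remove a probe that then fails the filter on missing values. The plain mean of Jmjd6 at E11.5 moved at most to -0.77. Rab3gap1 passed without array 10, at -2.85.

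Jmjd6 also lay across 0 from its reported value elsewhere. At E11.5 its probe 2 alone gave 0.0024. At E13.5 it was at -0.38 with floored values kept, -0.091 centred on bright probes and -0.19 without the arrays that stand apart. Its difference between E12.5 and E11.5 was 0.011 with arrays scaled to 1 spread, 0.43 with low-number ratios removed and 0.27 without the arrays that stand apart. The correlation between E12.5 and E13.5 was -0.0434 with the mutant in Cy5 at the first age against Cy3 at the second, -0.0542 with these exchanged and 0.102 without the arrays that stand apart. Between E11.5 and E13.5 it was -0.0466 with Cy5 against Cy3 and -0.0694 without those arrays.

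For the differences between ages, the sign turned gave 0.018, 0.068 and -0.10 for ribosomal protein, oxidative phosphorylation and hepatocyte and yolk sac genes between E13.5 and E12.5, none past the threshold, and -0.052 and 0.082 for the first 2 between E13.5 and E11.5. With an estimated correlation the ribosomal protein and oxidative phosphorylation differences of 0.86 and 0.50 from E12.5 and of 0.76 and 0.34 from E11.5 did not pass. The oxidative phosphorylation difference from E11.5 also did not pass with probes on every array (0.60) or assumed sets averaged (0.34), and lay at -0.011 centred on bright probes. With 1 array left out the differences from E12.5 ran from 0.71 to 0.96, 0.49 to 0.67 and -0.51 to -0.24, and those from E11.5 from 0.66 to 0.84 and 0.30 to 0.50.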

Other observations

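Neural progenitor genes at E13.5, which include transcription factors and growth factors of the early nervous system, had a median of 0.32 with 14 of 18 above 0 and adjusted p = 0.0823. Imprinted growth genes had a median of 0.31 with 9 of 13 above 0 and adjusted p = 0.0898. Craniofacial and palate genes lay at -0.30 with 6 of 7 below 0 and adjusted p = 0.199, and lens and retina genes at -0.21 with 10 of 12 below 0 and adjusted p = 0.248. None of these groups passed as tested, but neural progenitor genes passed with low-number ratios removed, at 0.68 with 11 of 11 above 0 and adjusted p = 0.00578, with every probe the fit could estimate, at 0.37 with adjusted p = 0.0122, with the 4 arrays alone, at 0.31 with adjusted p = 0.0263, and without array 1, which stands apart, and the E12.5 arrays that do, at 0.34 with adjusted p = 0.0193. Imprinted growth genes passed with the 4 arrays alone, with adjusted p = 0.0308, and without the arrays that stand apart, with adjusted p = 0.0455. With an estimated correlation the 2 groups had adjusted p = 0.261 and 0.374, and with the sign turned 0.671 and 0.726. At E12.5 cartilage and bone genes had a median of -0.30 with adjusted p = 0.412, and passed with low-number ratios removed, at -0.36 with adjusted p = 0.0492, and Cd68, a marker of macrophages, stood at -0.83 ± 0.28 (SE, n = 11 arrays) with adjusted p = 0.805.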
